A study of Mus musculus with 9 samples.

How the data were processed

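The values were intensities of a single-colour microRNA array, deposited by the authors as processed values, 1 column for each of 9 mouse lungs. Per the labels' protocols, total RNA was extracted with the miRNeasy mini kit and labelled with Hy5 by a miRCURY LNA labelling kit. The scanner software, background correction, normalization between arrays and detection rule are not given in the sources used here. The deposited intensities were linear and positive, and their median over the listed probes was between 10.03 and 10.23 on every array, which shows values already on a common scale whose construction stays unknown. Between 40 and 145 of the 739 probes had no listed intensity on an array.

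Each array was assigned to its group by its source label, which gave 9 groups of 1 array. With 1 array per group, no test, p-value or standard error was computed, and the number of arrays limits the precision. Comparisons were made as log2 differences between arrays, with counts of probes at least 2-fold higher or lower. The design was set before the data were examined. It called for the deposited scale where the medians over probes listed on all arrays differed by at most 1.5-fold, and for division by the 75th percentile over these probes otherwise. The medians over the 519 such probes differed by 1.61-fold, so each array was divided by its 75th percentile over them, which ranged from 90.49 to 144.2. Intensities printed in the text are the deposited values, while folds and log2 differences are on the percentile scale, so that the ratio of the printed intensities differs from the fold.

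The main set held the 369 of 739 probes with the highest mean log2 level over the 9 arrays, and in it no cell was missing. The lowest median intensity of a main-set probe was 6.05. Among the 739 probes, 5 carried several accessions, between 2 and 4 each, and were kept as single probes, 2 of them in the main set. All value columns of the table were used.

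The rule for named probes, set beforehand, took the 10 largest differences in each direction for each comparison. It also took the members of 11 lists of microRNAs, such as those linked to fibrosis, and of 10 lists of cell type markers. The files give mature microRNA accessions and do not pair them with names, and 0 accessions were found in the gene reference used here. The lists and markers could therefore not be matched, and their members and medians are not analysed here. For the same reason at most 2 accessions per direction are printed for each comparison. Further accessions were chosen after their values were seen where the text says so.

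For the comparisons that share the BLM and vehicle array, 1000 simulations of unchanged groups were made, with an error for each of 5 classes of probes by mean level. The error came from untreated wild type minus saline, and in later additions from siRNA on day 14 minus BLM with vehicle, and from the differences among the other 3 schedules. The first ranged over these classes from 0.49 to 0.86 (SD on the log2 scale for 1 array), the second from 0.13 to 0.22 and the third from 0.27 to 0.33. Expected overlaps of independent lists were computed from the list sizes and the 369 probes.

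The alternatives set beforehand were the deposited scale, quantile normalization and cyclic loess (limma), all probes, the 184 probes with the highest mean level, a pseudocount equal to the median of the scaled values (0.0871), thresholds of 1.5-fold and 3-fold, and the untreated wild-type lung in place of saline for the shares nearer to the reference. Added after the data were seen were the exchange of the reference lung in the counts for BLM and for the TG lung, the error taken from the day 14 array and from the other 3 schedules, each array in turn as the shared one, the schedules without day 14 and their simulation, and the other scalings and schedules of shared and opposite probes.

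The counting step was tested on simulated data for BLM with vehicle against saline over 369 probes, with a noise SD of 0.15 per array on the log2 scale. It called 30 of 30 probes simulated with a 2.5-fold difference, 39 of 39 with a 4-fold difference, 0 of 31 with a 1.3-fold difference, and 0 of 269 unchanged probes. This noise lay below the errors of 0.27 to 0.33 and of 0.49 to 0.86 above. The test therefore checks the counting and gives no rate of false or missed calls between these arrays. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.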

Results

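MicroRNA levels were measured in the lungs of 9 female C57BL/6 mice on single-colour arrays, to which total RNA labelled with the dye Hy5 was hybridised. Bleomycin (BLM), a cytotoxic antibiotic used to induce lung fibrosis in rodents, had been infused under the skin of 5 of these mice. Of these, 1 received vehicle into the trachea and 4 received small interfering RNA (siRNA) against TGFβ1, a growth factor that drives matrix production by fibroblasts. The siRNA was given at 5 mg/kg on days 3 and 7 (acute phase), on days 12 and 16 (chronic phase), on day 14 alone, or on days 3, 7 and 14 (both phases). Reference lungs came from a mouse infused with saline and from an untreated wild-type mouse. The remaining 2 mice were transgenic (TG) for human TGFβ1 carried on a bacterial artificial chromosome, and received either human TGFβ1 siRNA or vehicle into the trachea. Lungs were taken on day 21, or in week 4 from the TG mice. The TG and untreated wild-type mice were 12 weeks old and the others 9 weeks. Each group held 1 array, so there were no replicates, no test was run, and no difference could be set against a spread between animals of a group. The untreated wild-type and saline lungs, which had received neither BLM nor the transgene, were compared beforehand as a yardstick pair. They also differed in age and infusion, so their difference is no measure of the error between arrays.

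Of 739 probes, between 594 (siRNA on days 12 and 16) and 699 (TG with siRNA) had a listed intensity on an array, and the median of the listed intensities lay between 10.03 and 10.23 on every array. Probes are given by their mature microRNA accession, since the files do not pair accessions with microRNA names. Comparisons used the 369 probes with the highest mean level, with each array divided by its 75th percentile. The brightest probe on every array, MIMAT0011218, took 12.2% of the summed intensity after BLM with vehicle and 25.6% after siRNA on days 12 and 16. Over the 369 probes, the SD of the log2 differences between arrays was 0.23 for BLM with vehicle against siRNA on day 14, and 1.33 for untreated wild-type lung against siRNA on days 3, 7 and 14. These SDs are taken across probes within a pair of arrays and are not an error between animals.

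**Figure D1:**
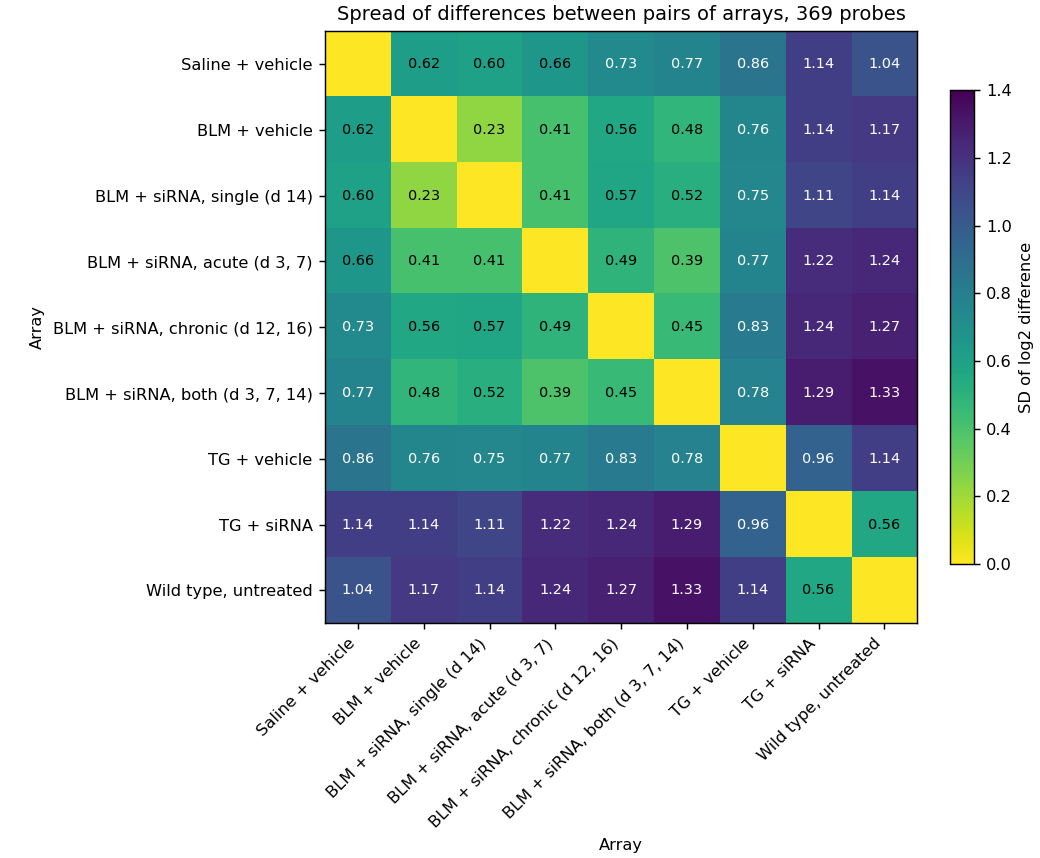
SD of the log2 differences over 369 probes (colour and printed value) for each pair of the 9 arrays, with the arrays on both axes. Within the arrays of BLM-treated mice the SDs lay between 0.23 and 0.57, the TG lung given siRNA and the untreated wild-type lung differed by an SD of 0.56, and each of those 2 differed from the other arrays by 0.96 or more.

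The lung after BLM with vehicle was compared with the saline lung to find the microRNAs that differed in fibrotic lung on day 21. By its source label the saline mouse received only the saline infusion, so the pair may also have differed in the intratracheal vehicle. MIMAT0000766 was 6.3-fold higher after BLM (intensity 78.4 against 10.9, log2 difference 2.65) and MIMAT0000530 was 6.1-fold higher (2979.6 against 427, log2 difference 2.61). MIMAT0000160 was 4.0-fold lower (162.6 against 568.4, log2 difference -2.0) and MIMAT0003457 was 2.45-fold lower (13.9 against 29.8, log2 difference -1.29, which fell short of 2-fold at -0.85 with a pseudocount). With the pseudocount MIMAT0000766 was at 1.92. In all, 22 probes were at least 2-fold higher and 13 at least 2-fold lower, or 9.5% of the 369, while 264 lay within 1.5-fold. The yardstick pair, untreated wild-type against saline lung, held 87 such differences. The split moved to 33 higher and 4 lower on the deposited scale, on which the median log2 difference lay 0.19 above that of the percentile scale, to 29 and 5 under quantile normalization and to 26 and 9 under cyclic loess.

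The 4 siRNA schedules were each compared with BLM and vehicle, the question being in which phase of the disease silencing of TGFβ1 acted best. After siRNA on days 3 and 7, MIMAT0000160 was 2.87-fold higher (446.5 against 162.6) and MIMAT0000549 2.11-fold higher (49.99 against 24.8), whereas MIMAT0000238 was 3.87-fold lower (8.17 against 33.1) and MIMAT0009399 3.13-fold lower (44.5 against 145.4). MIMAT0000549 fell short of 2-fold under quantile normalization (log2 difference 0.8) and with a pseudocount (0.82), and MIMAT0000238 was at -1.16 with the latter. With this schedule 3 probes were at least 2-fold higher and 8 lower, against 1 and 11 under quantile normalization. After siRNA on days 12 and 16, MIMAT0000371 was 3.99-fold higher (23.8 against 8.44) and MIMAT0011218 3.79-fold higher (138564 against 51728), whereas MIMAT0000145 was 3.94-fold lower (16.3 against 90.9) and MIMAT0000152 3.42-fold lower (92.9 against 449.7). The difference of MIMAT0011218 was lost under quantile normalization (log2 difference 0.0), which gives the brightest probe of every array the same value, and fell to 0.37 under cyclic loess, and that of MIMAT0000371 fell to 1.19 with a pseudocount. Here 14 probes were at least 2-fold higher and 18 lower. The deposited scale, whose median log2 difference lay -0.5 from that of the percentile scale, gave 6 and 36, quantile normalization gave 2 and 41, and cyclic loess gave 5 and 17.

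A single dose on day 14 left the profile closest to that of BLM with vehicle. Only MIMAT0000238 differed by at least 2-fold, being 3.48-fold lower (9.59 against 33.1, log2 difference -1.09 with a pseudocount), and 98.1% of the 369 probes lay within 1.5-fold. With doses on days 3, 7 and 14, MIMAT0000384 was 2.69-fold higher (60.3 against 22.01) and MIMAT0000144 2.26-fold higher (48.4 against 21.01), whereas MIMAT0003463 was 4.07-fold lower (12.5 against 50.1) and MIMAT0005856 3.6-fold lower (401.7 against 1422.9). MIMAT0000144 fell short of 2-fold under quantile normalization (log2 difference 0.99) and with a pseudocount (0.86), and MIMAT0003463 was at -1.38 with the latter. This schedule had 3 probes at least 2-fold higher and 21 lower, the same split as on the deposited scale. MIMAT0000238, lower under each of the other schedules, was not lower under this one (36.5 against 33.1, log2 difference 0.12).

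**Figure D2:**
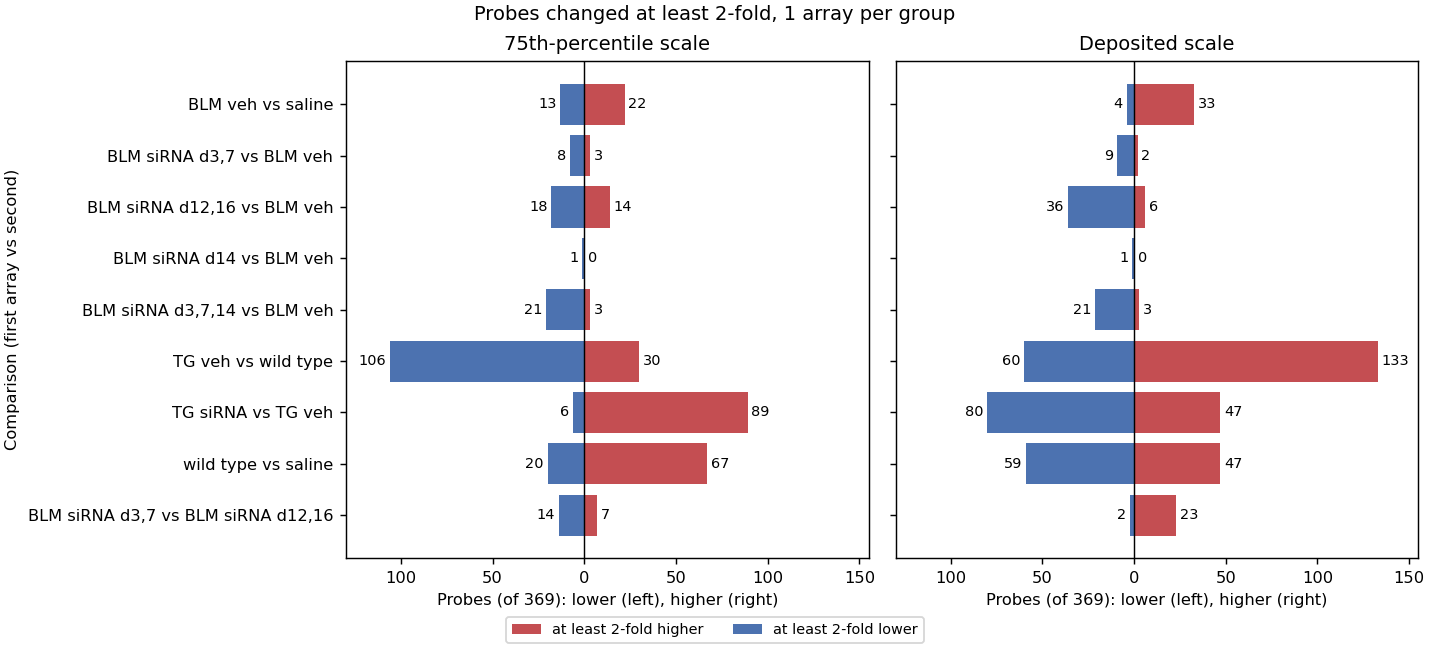
Number of probes, of 369, at least 2-fold higher (red, right) or lower (blue, left) in the first array than in the second for 9 comparisons with 1 array per group, on the percentile scale (left panel) and the deposited scale (right panel). TG with vehicle against untreated wild type gave 30 higher and 106 lower on the percentile scale but 133 and 60 on the deposited scale, and the direction of the excess also turned for TG with siRNA against TG with vehicle, for wild type against saline, and for days 3 and 7 against days 12 and 16.

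No probe differed from BLM with vehicle by at least 1.5-fold in the same direction under all 4 schedules. Since the 4 comparisons share the BLM and vehicle array, unchanged groups were simulated against it. The error set beforehand, from the yardstick pair, gave 40.1 such probes on average. That pair differed by an SD of 1.04, more than the schedules from BLM with vehicle (SD 0.23 to 0.56), so the 40.1 serves as no reference. Errors chosen after the data were seen gave 0.1 (from the day 14 array, the one closest to BLM with vehicle) and 5.5 (from the differences among the other 3 schedules, which may hold effects). Without the day 14 array, a choice made after the data were seen, 5 probes were higher and 10 lower under each of the other 3 schedules. For these 3 the simulations gave 57.3 with the error of the yardstick pair, 0.3 with that of the day 14 array, and 9.6 (95% of simulations between 4 and 16) with that among the schedules. With another array in the place of BLM with vehicle, the count of 15 became 6 for days 3 and 7, 28 for days 12 and 16, and 6 for days 3, 7 and 14. The 15 are therefore not read as an effect shared by the schedules, and part of them may come from the shared array. MIMAT0009399, with log2 differences of -1.64, -1.52 and -1.84 on days 3 and 7, days 12 and 16, and days 3, 7 and 14, was among those lower. It was lower by at least 1.5-fold in these 3 schedules under the other scalings too. MIMAT0011218 was among those higher, with 0.83, 1.92 and 0.72, but not under quantile normalization (0.0 in each) or cyclic loess (0.27, 0.37 and 0.22). The counts were 3 higher and 17 lower on the deposited scale, 2 and 16 under quantile normalization, and 3 and 9 under cyclic loess.

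The acute and chronic schedules were also compared with each other. MIMAT0011216 was 2.89-fold higher (3347.6 against 856.3) and MIMAT0000145 2.86-fold higher (62.95 against 16.3) after siRNA on days 3 and 7 than after days 12 and 16. MIMAT0000371 was 5.5-fold lower (5.85 against 23.8) and MIMAT0007863 2.86-fold lower (75.05 against 158.8), the former at a log2 difference of -1.37 with a pseudocount. The counts were 7 higher and 14 lower on the percentile scale, 23 and 2 on the deposited scale (median log2 difference shifted by 0.43), 23 and 4 under quantile normalization, and 9 and 6 under cyclic loess. The direction of the excess therefore depended on the scaling.

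Whether the BLM-associated differences lay closer to the saline level under siRNA was examined over the 35 probes that BLM with vehicle separated from saline by at least 2-fold. MIMAT0000530, 2.61 above saline on the log2 scale after BLM with vehicle, stood 2.5 above it after siRNA on days 3 and 7, 2.67 on days 12 and 16, 2.78 on day 14, and 2.53 on days 3, 7 and 14. MIMAT0000766 stood between 2.47 and 3.26 above saline under the 4 schedules, against 2.65 with vehicle. MIMAT0000160, which BLM with vehicle held 2.0 below saline, lay at -0.48 after days 3 and 7 and at -0.94 after days 3, 7 and 14, but at -1.85 after days 12 and 16 and at -1.66 after day 14. Of the 35 probes, 6 lay nearer to saline than to BLM with vehicle after days 3 and 7, 7 after days 12 and 16, 2 after day 14, and 5 after days 3, 7 and 14. These are 17.1%, 20.0%, 5.7% and 14.3%. Among the 22 higher probes they were 2, 3, 1 and 1, and among the 13 lower 4, 4, 1 and 4. In the median, between 83.8% and 95.7% of the BLM difference was left. Selection of the 35 probes on the BLM array alone moves probes back towards saline, and siRNA arrays simulated as equal to BLM with vehicle gave 1.3% with the error of the day 14 array and 15.1% (95% of simulations between 6.8% and 24.2%) with that among the other 3 schedules. The error of the yardstick pair, too large for these arrays, gave 38.5%. The simulated shares refer to other sets of probes than the 35, with 40.8, 61.1 and 131.3 probes selected on average in the same order, so the observed shares could not be ranked against them. On the deposited scale the share for days 12 and 16 was 32.4%, and for days 3, 7 and 14 it was 8.1%. Cyclic loess gave 11.4% for days 12 and 16, and quantile normalization 8.8% for days 3, 7 and 14. With untreated wild type as the reference, over the 120 probes that BLM with vehicle separated from it, the shares were 2.5%, 8.3%, 0.8% and 4.2%. The size of the shares and the order of the schedules therefore depended on these settings. The covariance of siRNA minus wild type with BLM minus saline, in which no array is shared, was 0.27, 0.25, 0.3 and 0.32 for the 4 schedules in the same order, beside a variance of 0.38 for BLM minus saline. That variance also holds the error of both arrays. TG with vehicle minus wild type, from mice without BLM, had a covariance of 0.22 with BLM minus saline. The covariances therefore give no share of the BLM difference that was kept.

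**Figure D3:**
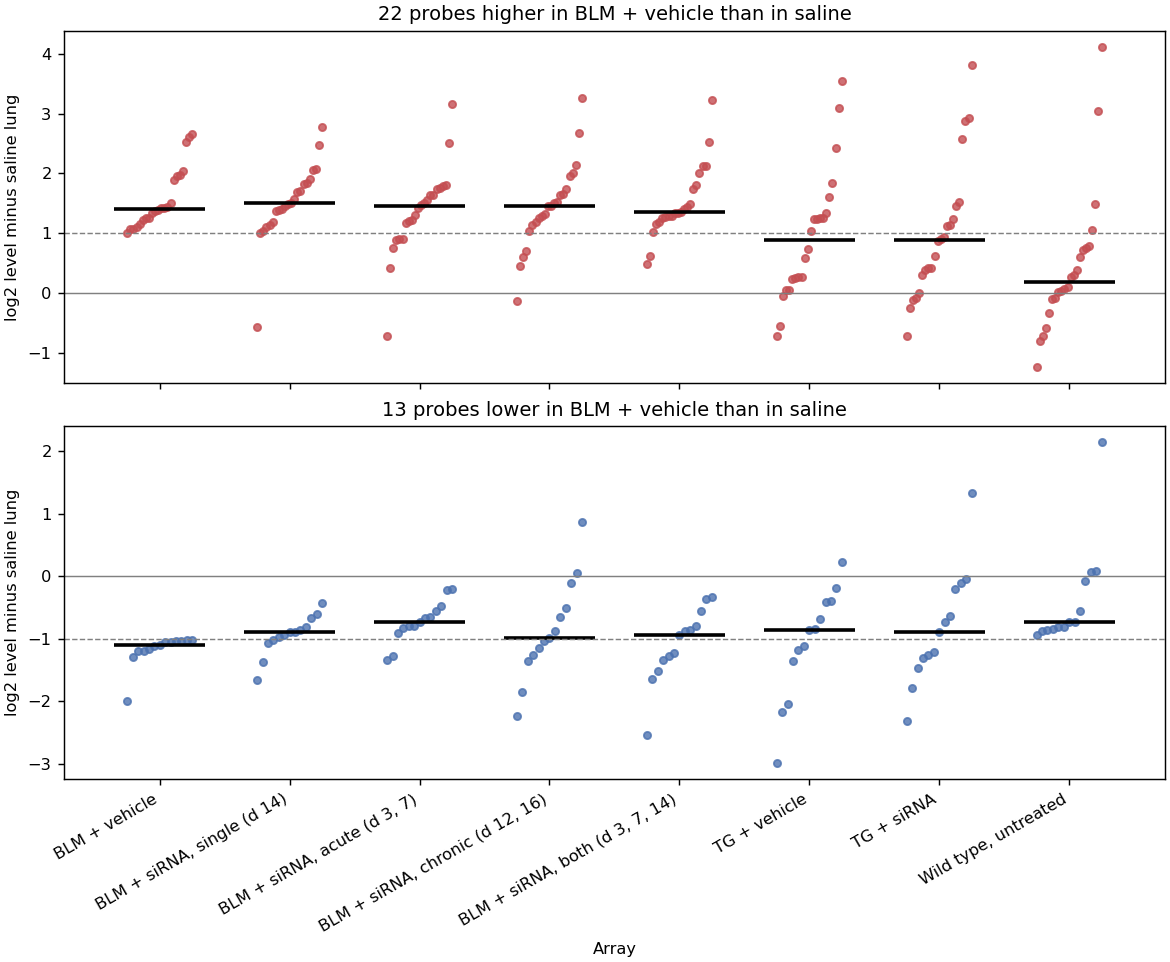
Log2 level minus that in saline lung for the 22 probes at least 2-fold higher (top) and the 13 at least 2-fold lower (bottom) after BLM with vehicle, in each of the other 8 arrays. Points are probes, sorted within each array, black bars are medians, dashed lines mark 2-fold, and the first column shows the array on which the probes were chosen.

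TG lung with vehicle was compared with untreated wild-type lung of the same age to find the microRNAs that differed with the transgene. The pair also differed in the intratracheal vehicle and in the sampling time. MIMAT0000530 was 5.04-fold higher in the TG lung (4596.6 against 575.1) and MIMAT0003475 4.87-fold higher (1412.5 against 182.9). MIMAT0003496 was 13.98-fold lower (27.2 against 239.6) and MIMAT0004635 8.74-fold lower (15.75 against 86.9). In this pair, 30 probes were at least 2-fold higher and 106 lower, or 36.9% of the 369. The deposited scale raised the median log2 difference by 0.66 and turned the split to 133 higher and 60 lower, while quantile normalization gave 50 and 75 and cyclic loess 55 and 63. The log2 difference of MIMAT0000530 was 2.33 on the percentile scale and lay between 2.02 and 3.0 under the other scalings, and that of MIMAT0003496, -3.81, lay between -3.14 and -3.97. That of MIMAT0003475 was 2.28 and lay between 1.61 (quantile normalization) and 2.95 (deposited scale), and that of MIMAT0004635 was -3.13, but -2.46 on the deposited scale, -2.32 under cyclic loess and -2.41 with a pseudocount. The reference lung mattered more. Against saline lung, a choice made after the data were seen, MIMAT0003496 was higher in the TG lung (1.45) and MIMAT0004635 was at -0.76. MIMAT0000530 was at 3.09 and MIMAT0003475 at 1.03. With that reference 91 probes differed at least 2-fold, 41 of them higher.

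The effect of the human TGFβ1 siRNA in the TG lung was examined against TG lung with vehicle. MIMAT0003468 was 13.2-fold higher (145.7 against 17.6) and MIMAT0003496 12.2-fold higher (207.6 against 27.2), which placed the latter near its intensity of 239.6 in untreated wild-type lung. In saline lung, however, the intensity of MIMAT0003496 was 7.85. MIMAT0003184 was 4.47-fold lower (3.95 against 28.2, a low intensity with the detection rule unknown) and MIMAT0005542 3.05-fold lower (63.9 against 310.2). The log2 difference of MIMAT0003184 was -2.16, but -1.11 with a pseudocount and -2.95 under cyclic loess. On the deposited scale that of MIMAT0003468 was 3.05 (3.72 on the percentile scale), that of MIMAT0003496 2.93 (3.61) and that of MIMAT0005542 -2.28 (-1.61). MIMAT0000530 stood 2.18 above untreated wild type on the log2 scale, against 2.33 with vehicle. The counts were 89 higher and 6 lower. On the deposited scale, with a median shift of -0.67, they were 47 and 80, under quantile normalization 55 and 18, and under cyclic loess 50 and 28. The log2 levels of the 369 probes had an SD of 2.86 in the TG lung with siRNA and 2.77 in untreated wild-type lung, against 3.04 or more on the other 7 arrays.

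In the yardstick pair itself, MIMAT0003496 was 38.2-fold higher in untreated wild-type than in saline lung (239.6 against 7.85) and MIMAT0000123 17.3-fold higher (101.4 against 7.35). With these dim saline values a pseudocount brought the log2 differences from 5.25 to 4.12 and from 4.11 to 2.99. MIMAT0003484 was 6.47-fold lower (1854.2 against 15006.5) and MIMAT0004528 5.1-fold lower (51.2 against 326.7), the former at a log2 difference of -2.69, or -2.09 under quantile normalization. In both TG lungs, too, MIMAT0003496 and MIMAT0000123 lay above and MIMAT0004528 below every array of the 9-week-old mice. At least 2-fold, 67 probes were higher and 20 lower. On the deposited scale, with a median shift of -0.32, 47 were higher and 59 lower, and under cyclic loess 46 and 34. Both lungs lacked BLM and the transgene, and with age and infusion differing the cause of their 87 differences was not tested.

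The models were set against each other in pairs of comparisons that share no array. MIMAT0000530 was at least 2-fold higher both after BLM and in the TG lung, the TG lung with siRNA included. Across the 369 probes, which are not independent replicates, BLM minus saline and TG with vehicle minus wild type had a covariance of 0.22 (Pearson r = 0.31, Spearman rho = 0.31). Of the 22 probes higher after BLM, 4 were also at least 2-fold higher in the TG lung, where independent lists would share 1.8, and of the 13 lower, 4 were also lower, where 3.7 would be shared. The shared higher probes numbered 17 on the deposited scale (11.9 by independent lists) and 11 under both quantile normalization and cyclic loess (3.9). The shared lower probes numbered 3 on the deposited scale (0.7), 3 under quantile normalization (1.0) and 4 under cyclic loess (1.5). For the siRNA effect, the Pearson r with TG siRNA minus TG vehicle was -0.24 for days 3 and 7, -0.12 for days 12 and 16, 0.1 for day 14, and -0.38 for days 3, 7 and 14. Of the 21 probes lower after siRNA on days 3, 7 and 14, none was at least 2-fold lower and 14 were at least 2-fold higher in the TG lung under siRNA, where 5.1 would be by independent lists. Under the other scalings 10 were of the 21 probes lower on the deposited scale (2.7 by independent lists), of the 18 under quantile normalization (2.7) and of the 17 under cyclic loess (2.3). Of the 8 probes lower after days 3 and 7, 1 was at least 2-fold higher in the TG lung under siRNA (1.9), and of the 18 lower after days 12 and 16, 7 were (4.3). The other scalings gave between 2 and 4 for days 3 and 7 (between 0.8 and 1.6) and between 8 and 15 for days 12 and 16 (between 2.3 and 6.1). TG siRNA minus TG vehicle had a covariance of 0.77 (r = 0.77, rho = 0.67) with untreated wild type minus saline, and 56 of the 89 higher probes were also at least 2-fold higher in that pair, where independent lists would share 16.2. Both lists held mostly dim probes, which that number leaves out of account, so it is too low as a reference. The shared probes numbered 34 on the deposited scale (6.0 by independent lists), 41 under quantile normalization (9.5) and 32 under cyclic loess (6.2).

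**Figure D4:**
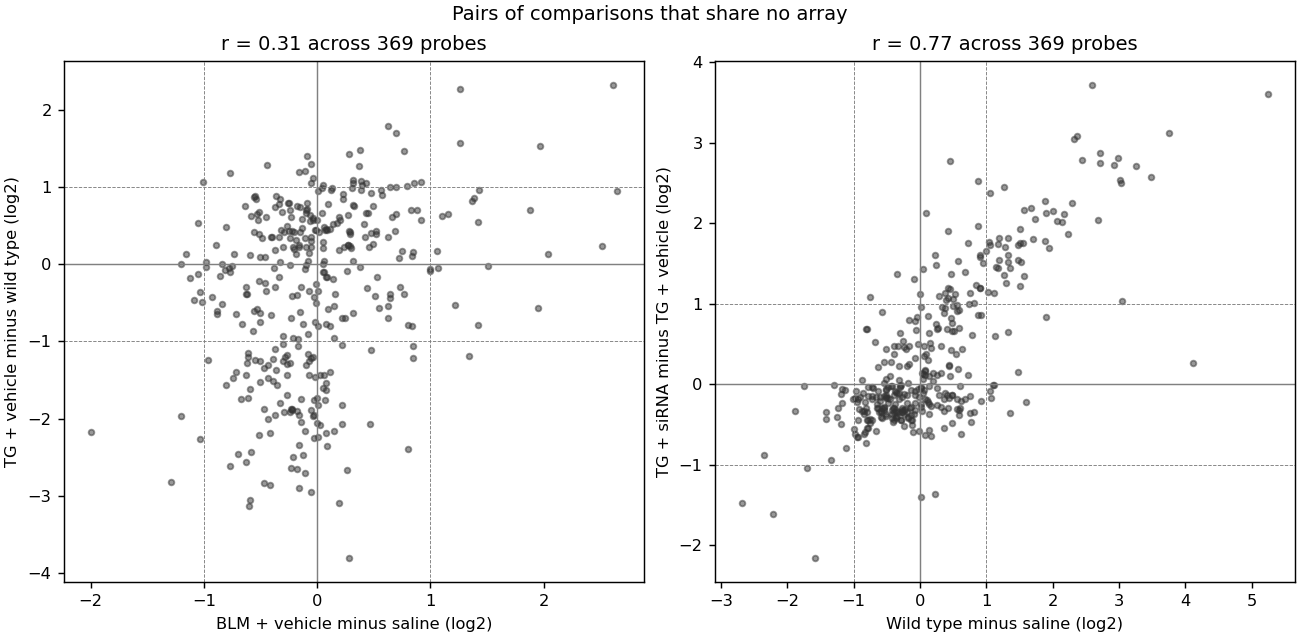
Log2 differences of 369 probes (points) in pairs of comparisons with no array in common, on the percentile scale. Left, BLM with vehicle minus saline (horizontal) against TG with vehicle minus untreated wild type (vertical), r = 0.31, and right, untreated wild type minus saline (horizontal) against TG with siRNA minus TG with vehicle (vertical), r = 0.77. Dashed lines mark 2-fold.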

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

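All tests in this part, and the probes named in it, were chosen after the results were seen.

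In 2 probes, siRNA against TGFβ1 went with differences of opposite sign in the 2 models, by at least 1.3-fold in each of the 4 BLM schedules and at least 2-fold in the TG lung. In the TG lung 89 of the 369 probes were at least 2-fold higher under siRNA. The number of opposite probes to be found by independent lists was not computed. MIMAT0003496 was lower than BLM with vehicle by log2 differences of -0.67 (days 3 and 7), -0.47 (days 12 and 16), -0.48 (day 14) and -1.59 (days 3, 7 and 14), and 3.61 higher in the TG lung with siRNA than with vehicle. Its intensities were low in the BLM arms, at 10.9 with vehicle and 6.57, 5.59, 7.88 and 3.68 under the schedules, beside an array median of 10.03 to 10.23, and the detection rule is not known. MIMAT0009399 was lower by -1.64, -1.52, -0.46 and -1.84 in the same order, and 1.76 higher in the TG lung, at intensities of 145.4 with vehicle and 44.5, 35.8, 106.7 and 41.3 under the schedules. The signs held under the 3 other scalings, but under quantile normalization MIMAT0009399 was at -0.29 on day 14, short of 1.3-fold. The 4 schedule differences share the BLM and vehicle array, so a high value on it alone would make all 4 negative. On that array MIMAT0009399 lay at 0.09 from saline and -0.64 from untreated wild-type lung (log2), and MIMAT0003496 at 0.28 and -4.97. MIMAT0009399 was thus not high beside these lungs, but neither of them had BLM. Untreated wild-type lung stood above saline lung by 5.25 for MIMAT0003496 and by 0.73 for MIMAT0009399. Higher levels of these probes were thus also seen in a pair given no siRNA. The difference between the models was not tested, since each group held 1 array.

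In 2 other probes, BLM and the transgene went with 2-fold differences of opposite sign. Such probes were no more than independent lists would share. Of those higher after BLM, 1 was lower in the TG lung, against 6.3 by independent lists. Of those lower after BLM, 1 was higher there, against 1.1. MIMAT0000538 was at -1.01 after BLM with vehicle against saline and at 1.07 in the TG lung with vehicle against untreated wild type, and MIMAT0004933 was at 1.34 and -1.19, from low intensities (7.44 against 2.57, and 11.7 against 16.9). The signs held under the 3 other scalings, but under each of these at least 1 of the 2 differences of both probes was below 2-fold, as with MIMAT0004933 in the TG lung, at -0.53 on the deposited scale, -0.48 under quantile normalization and -0.6 under cyclic loess. This was not tested either.

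Higher levels in the TG lung with siRNA than with vehicle recurred in the same probes as higher levels in untreated wild-type than in saline lung, with a covariance of 0.773 over 369 probes and no array in common. Scaling between arrays is argued against as the whole source, because quantile normalization and cyclic loess kept at least 80.3% of the covariance. The correlation within each of 5 classes of probes by mean level was at least 0.46. A trend between the classes is therefore argued against as the whole source. It was 0.84 in the dimmest class and 0.89 in the next. A narrower spread of levels on 2 of the arrays could also correlate the differences within a class. Quantile normalization gives the arrays the same distribution of levels, and left a covariance of 0.756 (r = 0.77). Cyclic loess, which removes trends with level between arrays, left 0.621 (r = 0.73). An unequal spread or a trend with signal level is therefore argued against as the whole source. The 89 higher probes were 1.27 higher (median log2, quartiles 0.75 and 1.95) in untreated wild-type than in saline lung, which restates the pattern. Left open is a return of the TG lung to the level of wild-type mice of its age, in line with an SD of 0.56 between TG with siRNA and wild type against 1.14 with vehicle, and a property shared by these 2 samples, such as RNA quality, since their log2 levels spread less (SD at most 2.86) than on the other 7 arrays (at least 3.04). With 1 array each these cannot be told apart.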

How the results depend on the processing

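The exchange of the reference lung in the counts, the simulation errors from the day 14 array and from the other 3 schedules, and the schedules without day 14 were tried only after the data were seen, and the other settings here were planned. Of 132 values of named probes under 3 other scalings and a pseudocount, 107 stayed within 1.5-fold of the value given, 25 moved further and 0 changed sign, and 7 values of 4 of the 33 named differences fell below 2-fold. In the counts at least 2-fold different, the 3 other scalings stayed within 1.5 times the main totals. The splits into higher and lower did not, except for day 14 and for days 3, 7 and 14. Thresholds and probe sets move counts by construction. In the order BLM, days 3 and 7, days 12 and 16, day 14, TG, TG siRNA, wild type against saline, and acute against chronic, all probes gave 87, 39, 125, 6, 249, 193, 166 and 64, and the 184 brightest probes 19, 7, 18, 0, 40, 21, 25 and 12, with 14 for days 3, 7 and 14. At 1.5-fold BLM gave 105, the schedules 47, 88, 7 and 56 (days 3, 7 and 14), TG 221, wild type against saline 170 and acute against chronic 69. At 3-fold these were 8 for BLM, 2, 8 and 9 for days 3 and 7, days 12 and 16, and days 3, 7 and 14, 67 for TG, 53 for TG siRNA, 39 and 1. The pseudocount, which shrinks differences of dim probes, gave 20 for BLM, 6, 19 and 15 for the 3 schedules of several doses, 87 for TG and 57 for TG siRNA. With untreated wild type as the reference, BLM gave 120, and with saline as the reference, TG gave 91. Probes alike in direction numbered 1 on the deposited scale, 4 with all probes and 15 without day 14. The share nearer to saline for days 3 and 7 was 37.3% with all probes, 10% with the pseudocount and 2.5% with the wild-type reference. For days 12 and 16 it was 32.4% on the deposited scale, 11.4% under loess, 46.2% with all probes, 10.5% with the 184 probes, 10% with the pseudocount and 8.3% with the wild-type reference. For day 14 it was 13.3% with all probes and 0.8% with the wild-type reference, and for days 3, 7 and 14 it was 8.1% on the deposited scale, 8.8% under quantile normalization and 4.2% with the wild-type reference. The covariance of the models was 0.132 with the pseudocount, against 0.219. That of siRNA in both models turned to 0.02 for days 12 and 16 with all probes (-0.064 before) and to -0.009 for day 14 with the 184 probes (0.023 before). Of 24 such values 7 others moved by over 1.5 times, to -0.056 for days 3 and 7 (-0.093 before) and -0.105 for days 3, 7 and 14 (-0.175 before) with the pseudocount, to -0.12 under quantile normalization and -0.17 with the 184 probes for days 12 and 16, and to between 0.001 and 0.003 for day 14. The simulated share nearer to saline was 1.3% with the day 14 error and 15.1% with the error among the other 3 schedules, against 38.5%. For the scalings, the reference lung and the covariances the cause was not tested. Other settings for list medians were not run, as the lists could not be matched. No paired analysis was possible because each group held 1 array, and no replicate could be left out. Between 40 and 145 of 739 probes had no listed intensity on an array, by a rule not given in the sources used here, and the 220 probes concerned could not be compared on all arrays.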

Other observations

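The tests in this part and the probes named in it were chosen after the results were seen.

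In some probes the 12-week-old mice (untreated wild type and both TG mice) stood apart from the 9-week-old mice. The whole profile did not part this way. Over the 369 probes, TG with vehicle lay nearer to the 9-week-old mice (SD 0.75 to 0.86) than to TG with siRNA (0.96) or untreated wild type (1.14). MIMAT0000123 lay between 81.9 and 109.1 in the 12-week-old and between 7.35 and 37.4 in the 9-week-old mice, and MIMAT0004528 between 42.7 and 124.8 against 238.2 and 497.9. Of the 369 probes, 27 were higher and 56 lower in all 3 arrays of the older mice than in any of the other 6, or 83 where chance gives 8.8 (2.38%). Of the 84 ways to part 9 arrays into 3 and 6, 1 separated as many, the real one, and the highest other count was 61, for untreated wild type, TG with siRNA and saline. On the deposited scale the split by age separated 67 probes and another split 68. The split was examined after the values were seen, and 5 of the 6 younger mice shared BLM, so the arrays are not exchangeable and chance stays open. Quantile normalization gave 75 probes and cyclic loess 92, so scaling as the whole source is argued against. Age may account for the separation of these probes. It stays open along with the absence of BLM and saline infusion in all 3 older mice, which the design joins to age.

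The reference lung mattered for single probes. MIMAT0003475, 1.26 above saline on the log2 scale after BLM with vehicle, was 2.51 above untreated wild type, and stood between 2.53 and 2.7 above it under the 4 siRNA schedules. MIMAT0003457, at -1.29 from saline after BLM with vehicle, was 2.14 above saline in untreated wild-type lung.

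In the TG lung with siRNA the higher probes were mostly dim ones. The median log2 difference from TG with vehicle fell over 5 classes of probes by mean level from 0.9 in the dimmest to 0.64, 0.04, -0.21 and -0.23 in the brightest. In untreated wild type minus saline the medians were 0.51, 0.47, 0.07, -0.32 and -0.35, and in TG with vehicle minus wild type -1.2, -0.76, -0.27, 0.38 and 0.45.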
